A study of Homo sapiens with 24 samples.

How the data were processed

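RNA of MonoMac6 cells was sequenced in 24 libraries, and per the labels these fall into 8 groups of 3: shNS and hairpins sh1, sh2 and sh3 against IGF2BP2 (12 libraries), shNS and shYTHDF2 (6 libraries), and DMSO and CWI1-2 (6 libraries). The labels call the RNA of the IGF2BP2 libraries total RNA and that of the others polyA RNA. For the YTHDF2 experiment they give 48 h of transduction and 3 days of selection. They give 2 mM glutamine in the medium for the YTHDF2 and CWI1-2 experiments and no value for the IGF2BP2 experiment. They do not say whether replicates are separate cultures.

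The authors deposited expected counts (estimated read counts) per gene, with no further normalization stated. Per the submitters' processing notes, FastQC 0.11.5, cutadapt 3.4, STAR 2.7.2b, RSEM 1.2.31 and DESeq2 1.32.0 were used with genome build hg38. The annotation release, strand setting and filters were not stated. Of all values, 3.48% were not whole, and they were rounded. The authors also deposited tables of log2 fold changes and p-values per the file headers, and whether those p-values were adjusted was not stated. The authors' tables were used for comparison only. The table of counts held 60651 entries with 59409 names; the 1361 entries with repeated names held at most 0.169% of a library's counts.

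Library totals ran from 7864252 to 10778442 counts. The 24 pairs of replicates within groups all differed by more than sampling noise, with chi-square per degree of freedom from 1.60 to 13.9. The highest values, 13.9, 6.81 and 4.27, were all between libraries labelled shYTHDF2, against 1.68 to 1.76 between the shNS libraries of that experiment. No other pair exceeded 3.35. CPM values, with library totals scaled by TMM factors, were computed here from the deposited counts. For genes with 1 to 3 counts in a whole control group the ratio is given with an exact 95% interval (Clopper-Pearson), which covers counting error only.

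Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood fit with robust = TRUE, two-sided tests), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 12 libraries of the IGF2BP2 experiment were fitted together with 4 group means, which gave each hairpin against shNS, the mean of the 3 hairpins against shNS, and an F test of differences between hairpins. The other experiments were fitted alone, each against its own control. Shared calls were counted beside the product of the shares, and genes called in one experiment were tested as sets in another.

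The groups, tests, alternatives, 33 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover glutamine uptake and metabolism, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, serine and one-carbon metabolism, the ATF4 stress response, the unfolded protein response, the tricarboxylic acid cycle, the nuclear-encoded respiratory chain, mitochondrially encoded messages, glycolysis, hypoxia, cholesterol synthesis, G1/S and DNA replication, mitosis, histones, p53 targets, apoptosis, monocyte and granulocyte differentiation, the KMT2A programme, interferon-stimulated genes, NF-kappaB and cytokines, class II antigen presentation, immediate-early genes, heat shock, NRF2 and xenobiotic response, autophagy and lysosome, m6A factors, messenger RNA decay, and markers of T and natural killer cells, B cells, erythroid cells and megakaryocytes, and epithelial and stromal cells. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 89 list tests of the 3 main comparisons. Of these, 51 passed, and 35 passed with an estimated correlation. The genes of 3 list entries were found under older symbols.

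Named genes are IGF2BP2, YTHDF2, their relatives IGF2BP1, IGF2BP3, YTHDF1 and YTHDF3, and MYC, GPT2 and SLC1A5; the 10 largest rises and 10 largest falls of each main comparison among protein-coding genes with a mean of at least 5 CPM and every treated library beyond every control library, for IGF2BP2 also called with each hairpin; per list at most 4 called members with the largest changes, or the 2 most abundant where none was called; 5 genes per direction of each shared set; and the 5 genes with the smallest p between hairpins. Some genes that this rule picks are not reported here.

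On simulated data with 200 changed genes, edgeR recovered 68.7%, 86.6% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold for the mean of the hairpins, 59.7%, 83.6% and 100.0% for shYTHDF2 and 79.1%, 83.6% and 98.5% for CWI1-2. Unchanged genes made up 5.68%, 7.95% and 9.38% of the calls, above the nominal 5%. A list raised in these data was called in all 3 main comparisons, and so were 2 lists that share genes with it.

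The alternatives were DESeq2 size factors, library totals, DESeq2 1.42.0, limma-voom, other filters, a 1.5-fold threshold, an adjusted p threshold of 0.01, a replicate block, only the groups compared, all 24 libraries in one fit, list tests with fry or an estimated correlation, single hairpins, and leaving out each library. Positions and transcript sequences came from GENCODE v29 on GRCh38. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for sequence scans and figures. No library was left out.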

Results

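RNA sequencing gave an estimated read count per gene for 24 libraries of MonoMac6, a human acute myeloid leukaemia cell line of the monocytic type. The libraries form 8 groups of 3. In the first experiment, 3 hairpins against IGF2BP2 (sh1, sh2 and sh3) stand beside a control hairpin with no target (shNS). In the second, cells labelled shYTHDF2 stand beside their own shNS control. In the third, cells treated for 48 h with CWI1-2 at 0.5 µM, a compound known as an inhibitor of IGF2BP2, stand beside cells given the solvent DMSO. Library totals ran from 7864252 to 10778442 counts, and 18586 to 20475 genes per library had a count. The 3 libraries with sh2 had counts for 20074 to 20475 genes, against 18809 to 19152 in the other libraries of that experiment. Values are counts scaled to library size (CPM) as group mean ± SD with n = 3, and log2 fold changes ± SE. A gene or gene list is said to have risen or fallen where its adjusted p was below 0.05.

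The comparison of the IGF2BP2 hairpins with shNS asks which transcripts depend on IGF2BP2, a reader of the RNA mark N6-methyladenosine (m6A) that is known to stabilise messages it binds, and whether genes of glutamine use are among them. With each hairpin the cells lost most of their IGF2BP2 mRNA and had less MYC, GPT2 and SLC1A5. Genes of amino acid supply fell together, among them ASNS, PSAT1 and CHAC1. Genes of monocytes and macrophages rose, among them ITGAM, which encodes the surface marker CD11b, while the granule enzyme MPO fell.

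IGF2BP2 (ENSG00000073792.15, GRCh38 chromosome 3, 185643739 to 185825056, minus strand) stood at 132 ± 5.80 CPM with shNS. It stood at 19.4 ± 2.24 CPM with sh1, 34.6 ± 1.35 CPM with sh2 and 18.6 ± 0.971 CPM with sh3, and the mean of the 3 hairpins was 5.68-fold lower (log2 -2.51 ± 0.05, adjusted p = 4.19e-40). MYC (ENSG00000136997.17, chromosome 8, 127735434 to 127741434, plus strand), a driver of growth, was at 369 ± 6.51 CPM with shNS and at 109 ± 5.6, 152 ± 0.783 and 185 ± 6.62 CPM with the 3 hairpins in order. GPT2 (ENSG00000166123.13, chromosome 16, 46884378 to 46931297, plus strand), a mitochondrial transaminase that makes alpha-ketoglutarate from glutamate, fell by 1.52 on the log2 scale with sh1, by 0.92 with sh2 and by 3.36 with sh3, from 77.4 ± 6.22 CPM. SLC1A5 (ENSG00000105281.12, chromosome 19, 46774883 to 46788594, minus strand), a glutamine transporter, fell from 638 ± 12.4 CPM by 1.11, 0.99 and 1.16 on the log2 scale. Over the mean of the hairpins the adjusted p was 5.38e-38 for MYC, 9.59e-32 for GPT2 and 1.22e-35 for SLC1A5. YTHDF2, another m6A reader, did not pass (log2 -0.10 ± 0.05, adjusted p = 0.0547; with sh2 it passed, -0.22), and it passed without sh1 replicate 3 (-0.13), sh2 replicate 1 (-0.13), sh3 replicate 1 (-0.11) or shNS replicate 2 (-0.14). Its relative YTHDF1 fell by 0.22 over the mean, without a call for sh1 (-0.06). YTHDF3 rose by 0.18, with a call for sh1 only (0.37, against 0.07 and 0.09 with sh2 and sh3), and its call over the mean was lost without shNS replicate 2 (0.11). The IGF2BP2 relative IGF2BP3 was at 1.60 CPM with shNS and did not pass over the mean (log2 0.65 ± 0.29, adjusted p = 0.0562), though it rose with sh2 (1.28). It passed without sh2 replicate 3 (0.71) or shNS replicate 3 (1.00). IGF2BP1 had too few counts to be tested in any comparison.

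**Figure D1:**
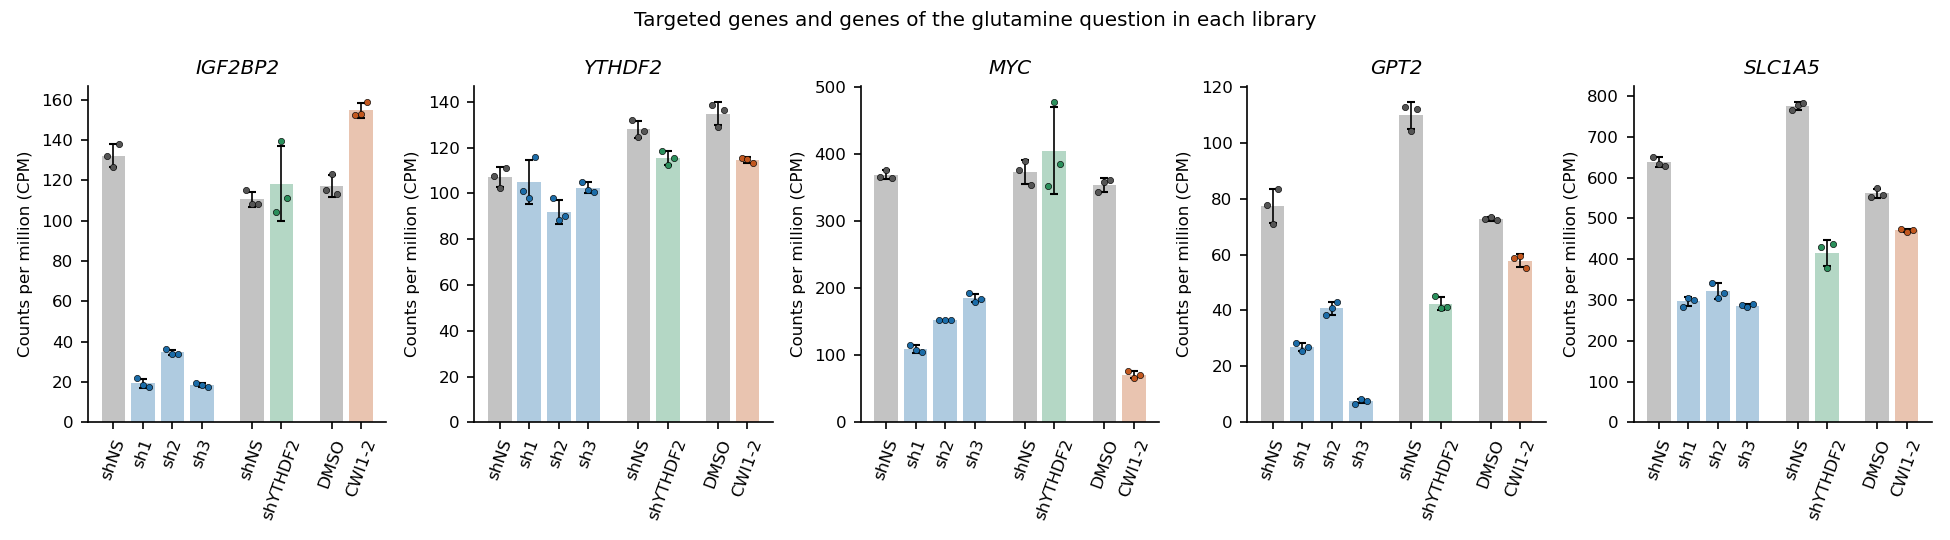
Scaled counts (CPM) of IGF2BP2, YTHDF2, MYC, GPT2 and SLC1A5 in each of the 24 libraries (points), with the mean (bar, from 0) and SD (error bar) of each group of 3; each panel has its own scale. IGF2BP2 lies at 18.6 to 34.6 CPM with the 3 hairpins against 132 CPM with shNS, and YTHDF2 lies at 115 CPM in the libraries labelled shYTHDF2 against 128 CPM in their shNS libraries.

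Over the mean of the 3 hairpins, 3467 of 14367 tested genes rose and 4145 fell (785 and 788 when fitted as 9 libraries against 3, which counts differences between hairpins as spread), and 1024 rose and 1205 fell with each of the 3 hairpins. The largest rises shared by the hairpins included SULF2, a heparan sulfatase (log2 3.26 ± 0.27, 0.627 to 7.99 CPM), KLF2, a zinc finger factor of quiescence (2.92 ± 0.07, 16 to 155 CPM), and TREM1, a receptor of myeloid cells that amplifies inflammation (2.80 ± 0.25). GNG11, a G protein subunit (2.75 ± 0.12), LILRB3, an inhibitory leukocyte receptor (2.61 ± 0.17), the scavenger receptor gene COLEC12 (2.60 ± 0.08), RGS2, a brake on G protein signalling (2.49 ± 0.09), and ENPP2, which encodes autotaxin (2.47 ± 0.12), rose as well. The size depended on the hairpin: ENPP2 rose by 1.47 with sh1, 5.04 with sh2 and 0.91 with sh3, and RGS2 by 3.85, 2.83 and 0.77. The largest falls were in CHAC1, a glutathione-degrading enzyme of the amino acid stress response (-3.45 ± 0.08, 64.3 to 6.54 CPM), ALDH1L2, a mitochondrial folate enzyme (-3.09 ± 0.10), ASNS, asparagine synthetase, which uses glutamine (-2.70 ± 0.05, 157 to 24.6 CPM), and ADM2, a peptide hormone (-2.68 ± 0.13). CTH, CBS and CBSL, of cysteine synthesis, fell by 2.62, 2.32 and 2.66, although CBS and CBSL are near-identical copies whose reads cannot be told apart with certainty.

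**Figure D2:**
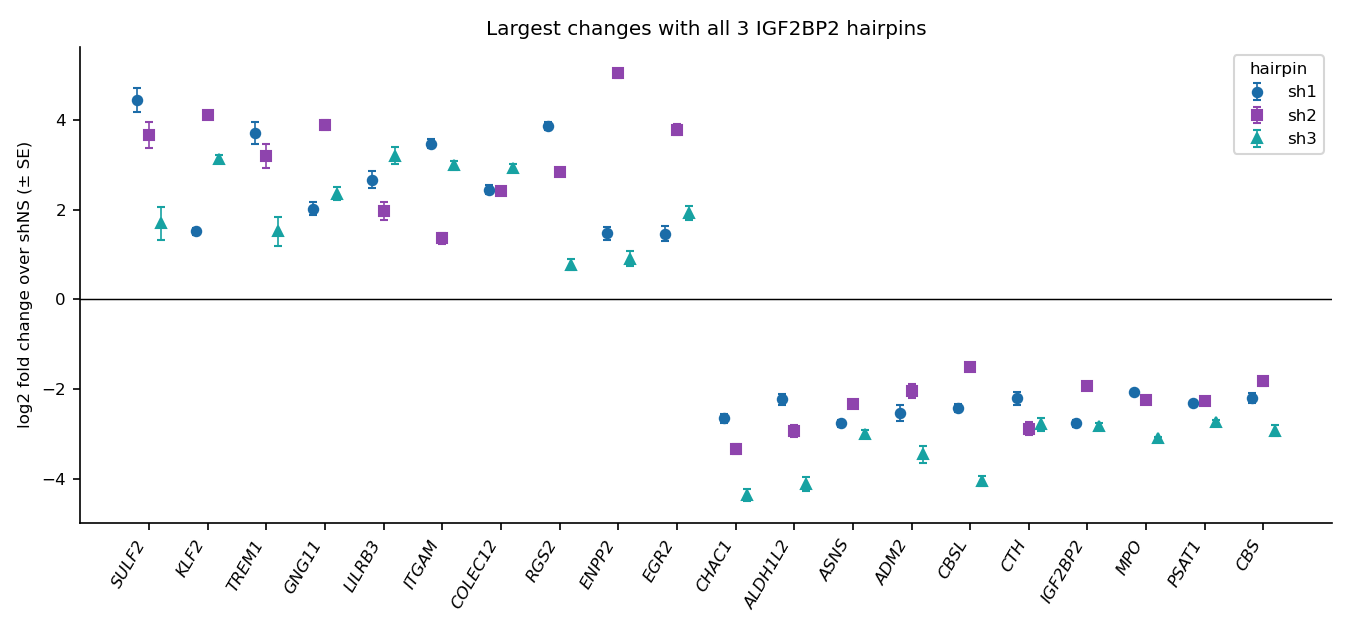
Log2 fold change over shNS (points, error bars SE, 3 libraries per group) for the 20 protein-coding genes with the largest changes shared by all 3 IGF2BP2 hairpins, by hairpin. All points of the first 10 genes lie above 0 and all of the last 10 below it, with KLF2 at 1.51, 4.11 and 3.13 and MPO at -2.06, -2.25 and -3.09 for sh1, sh2 and sh3.

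Genes of amino acid supply fell as groups. Of 25 tested members of the list for glutamine uptake and metabolism, 2 rose and 21 fell (median log2 -0.44, camera adjusted p = 2.01e-20). SLC38A1, a glutamine transporter, fell from 3.94 to 0.302 CPM, while GFPT2 (2.74) and GFPT1 (0.54), which pass glutamine nitrogen to hexosamines, rose. In the list for the response driven by ATF4, the transcription factor of amino acid shortage, 22 of 24 members fell and 2 rose (median -1.20, adjusted p = 2.73e-82), the 2 being ATF3 (0.46) and PPP1R15A (0.26). With all 24 libraries fitted together, the DMSO libraries also lay below the shNS libraries of this experiment (median log2 -0.84, 23 of 24 genes lower). The RNA labels of these groups differ (polyA and total RNA), so handling and a raised control cannot be told apart. The part of the fall that stems from the control was not tested. For serine and one-carbon metabolism the counts were 3 higher and 11 lower of 15 (median -0.64, adjusted p = 9.27e-32), with PSAT1, an enzyme of serine synthesis, falling by 2.43. These lists are not independent. ASNS, SLC7A5 and SLC3A2 are on both the glutamine and the ATF4 list, and PSAT1 and PHGDH on both the serine and the ATF4 list. Here and in the lists that follow, counts adjusted over the list alone equalled those over all genes tested unless given.

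Growth genes fell next to them. The list of MYC targets and ribosome biogenesis had 1 member higher and 49 lower of 52, or 2 and 49 adjusted over the list alone (median -0.49, adjusted p = 1.06e-15). PUS1, a pseudouridine synthase, fell by 1.03, and the member that rose was NOP2, a nucleolar methyltransferase (0.23), not called with sh1 (0.15), whose call was lost without shNS replicate 2 (0.16). Of 52 cytosolic ribosomal protein genes 35 fell and 0 rose (median -0.16, adjusted p = 1.16e-06, but adjusted p = 0.397 with an estimated correlation), RPL4 by 0.15, 1.56 and 0.46 with sh1, sh2 and sh3. With sh1 alone the ribosomal list leaned the other way (adjusted p = 0.330). The genes of the G1/S transition and DNA replication had 5 higher and 17 lower of 29 (median -0.22, adjusted p = 0.0453, and adjusted p = 0.194 with an estimated correlation), with the licensing factor gene CDT1 falling by 0.75; the call was lost without shNS replicate 1 (adjusted p = 0.0539), and no single hairpin gave it (adjusted p = 0.0601, 0.0979 and 0.242). Cholesterol synthesis had 2 higher and 15 lower of 21, or 3 and 15 adjusted over the list alone (median -0.24, adjusted p = 0.00478), HMGCS1, an early enzyme of the pathway, changing by -0.68, 0.24 and -0.94 with sh1, sh2 and sh3; with sh2 alone the list leaned upward (adjusted p = 0.657). Of 19 p53 target genes 10 rose and 5 fell (median 0.25, adjusted p = 0.000110). The growth inhibitor genes BTG2 (128 to 577 CPM) and CDKN1A (44.2 to 133 CPM) rose, and BBC3, which encodes the death protein PUMA, fell by 0.63. Replication-dependent histone genes had 10 higher and 0 lower of 16 (median 0.71, adjusted p = 0.00773), H2BC4 rising by 1.27, without a call for sh1 alone (adjusted p = 0.313) or sh2 alone (adjusted p = 0.232).

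Genes of mature myeloid cells moved apart. In the monocyte and macrophage list 22 of 25 members rose and 2 fell (median 0.86, adjusted p = 4.32e-28). ITGAM rose from 7.76 to 55.8 CPM, while TLR2, a receptor for bacterial lipoproteins, fell by 0.69. IRF8, a factor of monocyte fate, fell by 0.57 with sh1 and 0.48 with sh3 and rose by 0.26 with sh2. The granulocyte and granule list had 3 higher and 6 lower of 11 (median -0.14, adjusted p = 1.49e-11). Its granule enzymes MPO and PRTN3 fell, MPO from 1748 to 331 CPM and PRTN3 from 424 to 139 CPM, and CEBPE, a factor of late granulocytes, rose with sh1 only (2.39, against -0.27 and 0.19 with sh2 and sh3, not called). Immediate-early genes had 17 higher and 1 lower (MYC) of 19 (median 1.11, adjusted p = 5.59e-38), EGR2 rising by 2.39. For interferon-stimulated genes the counts were 21 higher and 2 lower of 31 (median 0.63, adjusted p = 0.000120), with OAS2, a sensor of double-stranded RNA, rising by 2.67 to 1.98 CPM; sh2 alone gave no call (adjusted p = 0.112). The NF-kappaB and cytokine list had 13 higher and 6 lower of 23 (median 0.56, adjusted p = 0.000526), the chemokine gene CXCL3 rising by 2.11; with sh3 alone it leaned downward (adjusted p = 0.0675). Lists for NRF2 and xenobiotic response (14 higher and 4 lower of 22, median 0.44, adjusted p = 4.12e-05) and autophagy and lysosome (17 and 2 of 24, median 0.45, adjusted p = 1.15e-09) also rose, NQO1, an antioxidant enzyme gene, by 1.39 and CTSD, a lysosomal protease gene, by 1.19, neither list with sh2 alone (adjusted p = 0.378 and 0.555). The heat shock list had 7 higher and 3 lower of 14, or 8 and 3 adjusted over the list alone (median 0.16, adjusted p = 0.00316, and adjusted p = 0.0554 with an estimated correlation), with the chaperone gene HSPA1A rising by 0.86. The m6A list, which holds IGF2BP2 itself, had 4 higher and 12 lower of 23, or 6 and 13 adjusted over the list alone (median -0.10, adjusted p = 0.0254, and adjusted p = 0.238 with an estimated correlation), FMR1, an RNA-binding protein gene, rising by 0.58; sh2 alone gave no call (adjusted p = 0.464).

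Other lists did not pass. The counts higher and lower were 10 and 7 of 19 for the unfolded protein response (adjusted p = 0.991; the chaperone gene HSPA5 rose by 0.59 and EDEM1, of protein disposal, fell by 0.76) and 3 and 10 of 21 for the tricarboxylic acid cycle (adjusted p = 0.0520, MDH2, malate dehydrogenase, falling by 0.13, 2.01 and 0.10 with sh1, sh2 and sh3). They were 14 and 13 of 37 for the respiratory chain, or 15 and 13 adjusted over the list alone (adjusted p = 0.847), 2 and 6 of 13 for mitochondrially encoded messages (adjusted p = 0.198) and 11 and 5 of 23 for glycolysis (adjusted p = 0.0947). Hypoxia genes had 4 and 7 of 15 (median -0.15, mean 0.02, test downward, adjusted p = 0.30), with VEGFA, a vessel growth factor gene, falling by 0.93. Mitosis had 11 and 8 of 29 (adjusted p = 0.644), regulators of apoptosis 11 and 3 of 23 (adjusted p = 0.543) with BCL2, a survival gene, falling from 94.7 to 29.1 CPM, and messenger RNA decay 3 and 16 of 29 (adjusted p = 0.0660). The leukaemia programme of KMT2A-rearranged cells had 12 and 5 of 21 (adjusted p = 0.158), HOXA7, a developmental factor gene, rising by 1.14 and FLT3, a growth receptor gene, falling by 0.61. Class II antigen presentation had 2 and 4 of 11 (median 0.04, mean -0.07, test downward, adjusted p = 0.583). Single hairpins disagreed for mitosis, which fell with sh1 (adjusted p = 0.00226) and rose with sh3 (adjusted p = 0.00556). They also disagreed for class II genes, which fell with sh1 (adjusted p = 0.0459) and rose with sh3 (adjusted p = 0.0131). With sh1 alone glycolysis rose (adjusted p = 0.00270) and hypoxia and messenger RNA decay fell (adjusted p = 0.00911 and 0.00849). With sh2 alone the tricarboxylic acid cycle and mitochondrially encoded messages fell (adjusted p = 0.0142 and 0.000494) and the KMT2A list rose (adjusted p = 1.25e-06). With sh3 alone the unfolded protein response rose (adjusted p = 0.0120).

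Markers of other cells were few. Epithelial and stromal markers had 4 higher and 1 lower of 7 (adjusted p = 0.488, and adjusted p = 0.00170 upward with sh3 alone), COL1A1, a collagen gene, rising by 2.01 over the mean with a call for sh2 only (3.73, against 1.01 and 1.31 with sh1 and sh3). Of 4 tested B cell markers CD79B rose by 1.27 over the mean, without a call for sh1 (0.34), and none of 3 erythroid and megakaryocyte markers passed. None of 3 T cell and natural killer cell markers passed over the mean, NKG7 among them (log2 0.09, adjusted p = 0.0954). By hairpin, NKG7 rose with sh1 and sh2 (0.72 and 0.39) and fell with sh3 (-0.85). TRAC, the constant part of the T cell receptor alpha chain, rose by 1.37 ± 0.33 with sh1 and 5.31 ± 0.20 with sh2, from 0.884 to 2.29 and 35.6 CPM, and had 0 counts in every library with sh3.

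The 3 hairpins did not act alike. In 11318 genes (78.8%) the hairpins differed (edgeR F test). SOCS3, a brake on cytokine signalling, changed by 2.16, 0.73 and -2.43 on the log2 scale for sh1, sh2 and sh3, IDH1, an isocitrate dehydrogenase, by 0.48, -1.76 and 0.47, PECAM1, an adhesion molecule, by 0.21, -1.07 and 1.17, and RPL14, a ribosomal protein, by 0.05 (not called), -2.42 and -0.35. Between pairs of hairpins, 1631 genes were higher and 1903 lower in both sh1 and sh2 with 2077 opposite, 2053 and 2058 in sh1 and sh3 with 898 opposite, and 1714 and 1933 in sh2 and sh3 with 1547 opposite. Across genes r was 0.26, 0.50 and 0.32 for these pairs, against 0.48, 0.51 and 0.50 in simulations without hairpin effects. The simulated changes held noise alone, so their r comes from the shared shNS libraries. It is no measure for the r of the data, where the changes were larger, and nothing is concluded from r. The covariance was 0.158, 0.229 and 0.176, against 0.0224, 0.0236 and 0.0224 in those simulations. The products of the shares gave 1197 and 1288, 950 and 1020, and 1098 and 1130 for the shared directions, and 295 and 321 for all 3 hairpins. All hairpins share the same 3 shNS libraries, and in 10 simulations without hairpin effects no gene was shared. The simulations held counting noise and the fitted spread between libraries of a group, so these alone gave no overlap at this threshold. A difference common to all 3 shNS libraries was not simulated, so the part of the excess that stems from shared controls is not known.

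Tests were made with edgeR, and p-values measure only the spread between these libraries, since the labels do not say that replicates are separate cultures. In the authors' table for IGF2BP2, all 197 genes are lower, 194 were tested here, and all 194 were lower with each hairpin. Of the 204 genes at least 1.5-fold lower with each hairpin here, 182 are in that table.

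The comparison of shYTHDF2 with its shNS control asks what the loss of YTHDF2 does, an m6A reader known to speed the decay of messages it binds. The YTHDF2 message itself was at 115 ± 2.96 CPM in the libraries labelled shYTHDF2 and at 128 ± 3.6 CPM with shNS. All 24 genes of the ATF4 stress list fell, and so did GPT2 and SLC1A5, while all 14 tested heat shock genes rose. MYC did not pass, yet 39 of 52 MYC targets and ribosome biogenesis genes rose. C3, of complement, THBS1, of cell adhesion, and HMOX1, of haem breakdown, had some of the largest rises.

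YTHDF2 (ENSG00000198492.15, chromosome 1, 28736621 to 28769775, plus strand) differed by log2 -0.15 ± 0.06 (adjusted p = 0.0594), and it passed without shYTHDF2 replicate 1 (-0.16). GPT2 fell from 110 ± 4.81 to 42.4 ± 2.35 CPM (log2 -1.37 ± 0.07, adjusted p = 2.03e-08) and SLC1A5 from 776 ± 9.23 to 415 ± 31.5 CPM (-0.90 ± 0.06, adjusted p = 1.45e-07). MYC was at 373 ± 18.2 and 405 ± 64.8 CPM (0.12 ± 0.10, adjusted p = 0.370), and passed without shYTHDF2 replicate 1 (0.21). IGF2BP2 did not pass (0.10 ± 0.10, adjusted p = 0.439), nor did IGF2BP3 (0.60 ± 0.38, adjusted p = 0.218). YTHDF3 rose by 0.34 ± 0.06 (adjusted p = 0.000897) and YTHDF1 by 0.19 ± 0.07 (adjusted p = 0.0391), a call lost without any of the 3 shNS libraries (0.16 to 0.23) or shYTHDF2 replicate 3 (0.15).

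In all, 2922 of 13562 tested genes rose and 2768 fell. Among the largest rises were C3, the central complement protein (log2 4.65 ± 0.18, 1.55 to 39.3 CPM), THBS1, the adhesion glycoprotein thrombospondin (3.97 ± 0.24), S100A12, a calcium-binding alarm protein of myeloid cells (3.21 ± 0.20), and HMOX1, which degrades haem (3.07 ± 0.14, 5.40 to 45.5 CPM). CNR2, a cannabinoid receptor of immune cells (2.82 ± 0.15), CD163, the haemoglobin scavenger receptor of macrophages (2.60 ± 0.25), KCTD12 (2.43 ± 0.09), GNG11 (2.37 ± 0.25) and TP53INP2, which takes part in autophagy (2.29 ± 0.08), rose as well. AC006064.6 rose by 2.85 ± 0.71 (adjusted p = 0.0288), a call lost without shNS replicate 1 or any of the 3 shYTHDF2 libraries (2.56 to 3.08). CHAC1 fell 64.1-fold, from 70.2 ± 0.747 to 1.07 ± 0.459 CPM (adjusted p = 5.82e-11). MOCOS, a molybdenum cofactor enzyme, fell by 4.36, ADM2 by 4.17, the glycine transporter gene SLC6A9 from 17.6 to 0.960 CPM, SPTB, a spectrin, by 3.95, CLGN, a chaperone, by 3.73, and STC2, a glycoprotein induced by stress, by 3.68 (153 to 12 CPM). ALDH1L2 fell by 3.66, SYTL1, of vesicle traffic, from 119 to 11.2 CPM, and MFAP4, of the extracellular matrix, by 3.39.

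**Figure D3:**
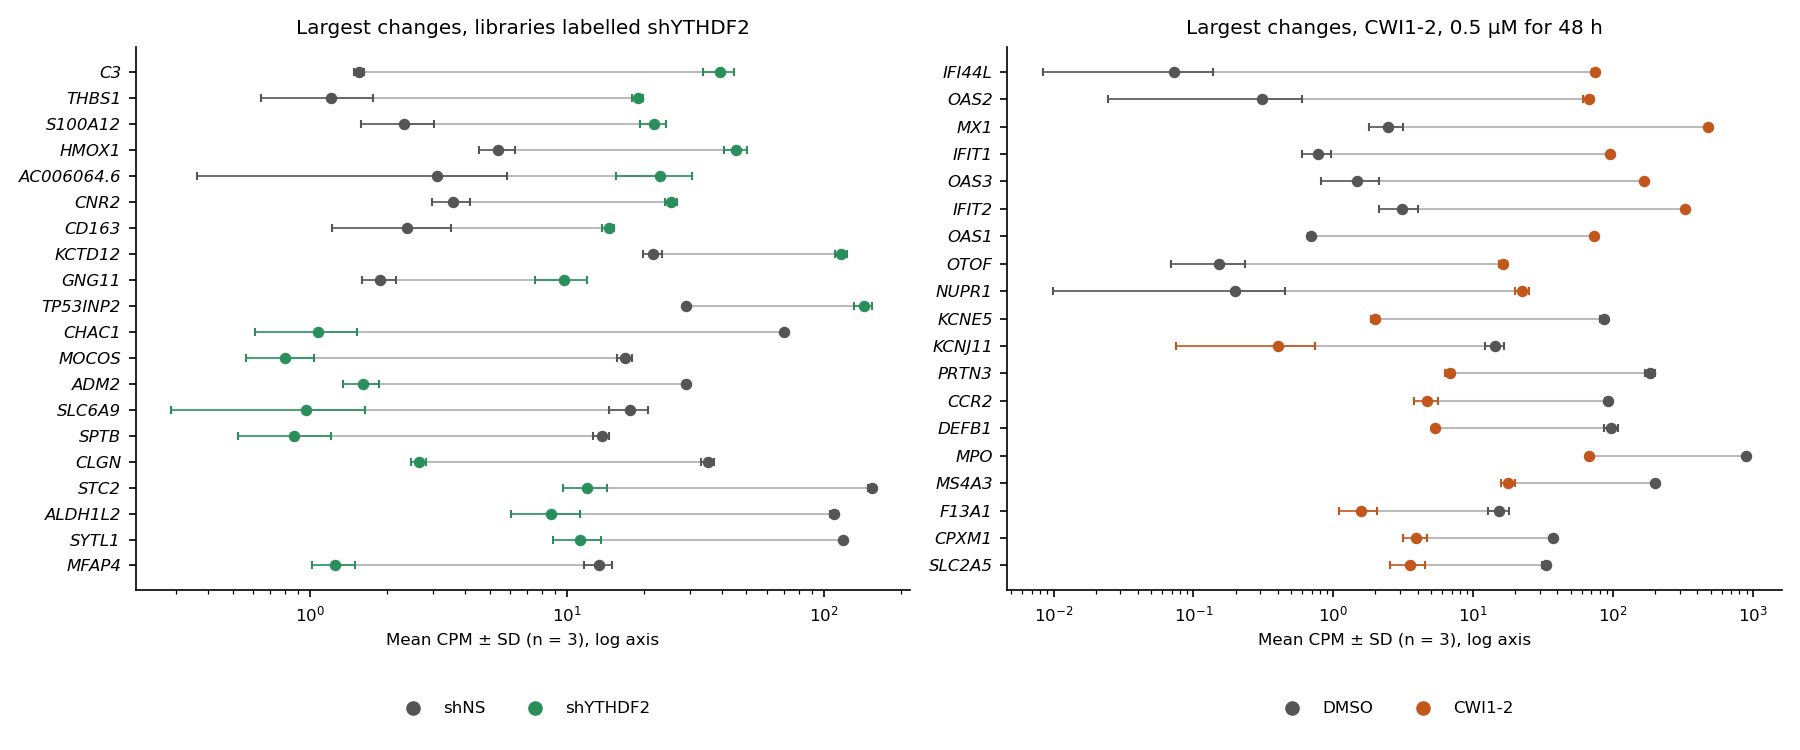
Mean scaled counts (CPM) ± SD (n = 3, log axis) of protein-coding genes with the largest changes in the libraries labelled shYTHDF2 (left) and under CWI1-2 (right), each with its control in grey. C3 lies at 1.55 CPM in shNS and 39.3 CPM in shYTHDF2 libraries, and MX1 at 2.48 CPM with DMSO and 477 CPM with CWI1-2; the DMSO error bar of NUPR1, which would reach below 0, is shortened.

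In the ATF4 list 0 members rose and 24 of 24 fell (median -1.91, adjusted p = 1.19e-125), among them the stress genes TRIB3 (386 to 41.2 CPM) and DDIT4 (481 to 54.1 CPM). This list lay 1.23 (median log2) higher in the shNS libraries of this experiment than in the DMSO libraries. Serine and one-carbon metabolism had 0 higher and 9 lower of 15 (median -0.75, adjusted p = 2.00e-21), with PHGDH, the first enzyme of serine synthesis, falling from 366 to 59.7 CPM and SHMT2, a mitochondrial enzyme of the same chain, by 1.53. Against the DMSO libraries the serine list had a median log2 of 0.80 in these shNS libraries, with 9 genes higher and 5 lower. In the shYTHDF2 libraries it had -0.26 (SE 0.13), with 0 higher and 12 lower. The glutamine list went both ways, with 9 higher and 12 lower of 26 (median 0.01, mean -0.34, test downward, adjusted p = 1.52e-05, but adjusted p = 0.0845 with an estimated correlation). ASNS fell by 3.01 and OAT, of ornithine metabolism, rose by 0.66. The glutamine and serine lists share genes with the ATF4 list, ASNS and PHGDH among them, so their calls are not independent of it. The hypoxia list had 2 higher and 6 lower of 11, or 2 and 7 adjusted over the list alone (median -0.27, adjusted p = 0.000110, and adjusted p = 0.0799 with an estimated correlation), VEGFA falling from 438 to 51.7 CPM. Of 19 p53 targets 2 rose and 9 fell (median -0.37, adjusted p = 0.000549, and adjusted p = 0.0880 with an estimated correlation), CDKN1A by 1.92 and BBC3 by 2.43.

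MYC targets and ribosome biogenesis genes had 39 higher and 3 lower of 52, or 40 and 5 adjusted over the list alone (median 0.43, adjusted p = 3.09e-09), with UTP20, of ribosome assembly, rising by 0.99 and EXOSC5, of the RNA exosome, falling by 0.65. With all 24 libraries fitted together this list differed from DMSO by a median log2 of -0.37 in the shNS libraries and -0.01 in the shYTHDF2 libraries. Of 52 ribosomal protein genes 0 rose and 41 fell, or 1 and 50 adjusted over the list alone (median -0.76, adjusted p = 5.16e-15, but adjusted p = 0.238 with an estimated correlation), RPL37 by 1.01. The heat shock list had 14 higher and 0 lower of 14 (median 1.07, adjusted p = 4.01e-26), HSPH1, a chaperone gene, rising from 98.8 to 324 CPM. Its level in the shNS libraries differed from that of the DMSO libraries by a median log2 of -1.56, and the shYTHDF2 libraries lay below DMSO as well (-0.48, 13 of 14 genes lower). The mitosis list had 19 higher and 1 lower of 29, or 20 and 1 adjusted over the list alone (median 0.39, adjusted p = 9.09e-06), CDC20, which triggers anaphase, rising by 0.79. The NRF2 list had 15 higher and 2 lower of 21, or 16 and 2 adjusted over the list alone (median 0.42, adjusted p = 1.50e-05), with SLC7A11, the cystine transporter, falling from 160 to 53.2 CPM against the direction of the list. The monocyte list had 12 higher and 6 lower of 25 (median 0.25, adjusted p = 0.000518), CD14, a receptor for bacterial lipopolysaccharide, falling by 1.07. The tricarboxylic acid cycle had 11 higher and 0 lower of 21, or 11 and 1 adjusted over the list alone (median 0.24, adjusted p = 0.000384, and adjusted p = 0.0520 with an estimated correlation).

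A further pair of lists passed only with the preset correlation. The unfolded protein response had 10 higher and 6 lower of 19 (median 0.20, adjusted p = 0.0352, and adjusted p = 0.134 with an estimated correlation), with the chaperone gene CALR rising by 1.41 and HERPUD1 falling by 1.86. The m6A list had 10 higher and 2 lower of 23, or 10 and 3 adjusted over the list alone (median 0.16, adjusted p = 0.0477, and adjusted p = 0.329 with an estimated correlation), the demethylase gene ALKBH5 rising by 0.53. Both calls were lost without shNS replicate 1 (adjusted p = 0.0639 and 0.0581) or shNS replicate 2 (adjusted p = 0.0553 and 0.0544), and the m6A call also without shYTHDF2 replicate 2 (adjusted p = 0.0663), the library whose mitochondrial messages took 5.0% of counts against 3.67% and 3.9% in the other two.

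Lists that did not pass had, higher and lower, 9 and 1 of 37 for the respiratory chain, or 5 and 1 adjusted over the list alone (adjusted p = 0.293), 2 and 1 of 13 for mitochondrially encoded messages, or 1 and 1 (adjusted p = 0.543; mitochondrial ribosomal RNA took 0.214 to 0.260% of counts against 0.519 to 0.525% with shNS), and 12 and 6 of 23 for glycolysis, or 13 and 7 (adjusted p = 0.116). LDHA, lactate dehydrogenase, rose by 1.33. They had 10 and 4 of 21 for cholesterol synthesis (adjusted p = 0.185), 4 and 8 of 29 for G1/S (adjusted p = 0.331), 4 and 0 of 9 for histones (adjusted p = 0.103) and 4 and 6 of 22 for apoptosis, or 4 and 7 (median -0.06, mean 0.01, test downward, adjusted p = 0.583). Granulocyte genes had 3 and 6 of 11 (median -0.47, mean 0.12, test downward, adjusted p = 0.0624), MPO falling by 1.16. The KMT2A list had 4 and 4 of 22 (median -0.04, mean 0.15, test upward, adjusted p = 0.673), interferon genes 1 and 9 of 26, or 1 and 8 (adjusted p = 0.103), the NF-kappaB list 9 and 5 of 20, or 10 and 5 (adjusted p = 0.160), and class II genes 1 and 5 of 9 (adjusted p = 0.0529). Immediate-early genes had 1 and 8 of 16 (adjusted p = 0.0728), autophagy and lysosome 12 and 4 of 24 (adjusted p = 0.112), messenger RNA decay 12 and 5 of 29, or 12 and 6 (adjusted p = 0.263), with UPF1, of nonsense-mediated decay, rising by 0.81, and epithelial and stromal markers 3 and 1 of 5 (adjusted p = 0.347). In these sentences the second pair of counts is the one adjusted over the list alone. Of the T cell, B cell and erythroid markers, 1, 1 and 2 were tested and none passed, while 1 B cell marker, EBF1 (log2 0.72), passed adjusted over the list alone.

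In the authors' table for YTHDF2 all 990 genes are higher, although the name of the table gives a negative log2 limit, as for lower genes. Of these, 948 were tested here, 947 had the same sign and 930 rose. The fall in YTHDF2 message did not pass the test, so the contrast is named here by its label only.

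The comparison of CWI1-2 with DMSO asks how the cells respond to the compound. Interferon-stimulated genes rose in 30 of 31 cases, MX1, an antiviral GTPase, from 2.48 ± 0.691 to 477 ± 7.98 CPM. All 52 genes of the MYC target list fell, MYC itself from 354 ± 10.1 to 71.2 ± 5.66 CPM. Granule genes of granulocytes fell, PRTN3 from 185 ± 14.5 to 6.77 ± 0.484 CPM and MPO from 888 ± 14.7 to 67.4 ± 2.13 CPM. Genes of NF-kappaB, NRF2 and ATF4 rose as groups, and mitochondrial, cholesterol and replication genes fell.

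MYC fell by 2.31 ± 0.04 on the log2 scale (adjusted p = 9.32e-52). IGF2BP2 rose from 117 ± 5.27 to 155 ± 3.62 CPM (0.40 ± 0.05, adjusted p = 3.42e-12). GPT2 fell by 0.33 ± 0.06 and SLC1A5 by 0.25 ± 0.03 (adjusted p = 2.87e-06 and 1.67e-11), from 72.8 and 561 CPM. YTHDF2 fell by 0.24 ± 0.05, YTHDF3 rose by 0.24 ± 0.05, and YTHDF1 did not pass (-0.06, adjusted p = 0.287). IGF2BP3 rose by 2.60 ± 0.36, from 0.731 to 4.5 CPM.

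Of 13466 tested genes, 4902 rose and 4866 fell. The largest rises were mostly in genes induced by interferon: IFI44L (0.0729 to 73.7 CPM), OAS2 (7.77 ± 0.20), OAS3 (6.86 ± 0.11) and OAS1 (6.70 ± 0.15) of the double-stranded RNA response, IFIT1 (6.94 ± 0.14) and IFIT2 (6.74 ± 0.08). IFI44L had 2 counts in the DMSO libraries together, so that its ratio of 1013 carries a counting interval of 280 to 8367 (95%). OTOF, known for vesicle release in the ear (6.69 ± 0.31), and NUPR1, a stress-induced nuclear protein (6.59 ± 0.28), rose as well. Besides MPO and PRTN3, the largest falls were in KCNE5, a potassium channel subunit (-5.41 ± 0.12, 85.4 to 1.98 CPM), KCNJ11, another potassium channel gene (-5.08 ± 0.29), CCR2, a chemokine receptor of monocytes (-4.28 ± 0.10), DEFB1, a defensin (-4.18 ± 0.10), and MS4A3, a marker of granulocyte-monocyte progenitors (-3.48 ± 0.06). F13A1, a clotting factor subunit, fell by 3.27, CPXM1 by 3.23 and the fructose transporter gene SLC2A5 by 3.23.

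Interferon-stimulated genes had 30 higher and 1 lower of 31 (median 3.30, adjusted p = 5.03e-74), the member that fell being BST2, a tether of viruses (230 to 166 CPM). The NF-kappaB and cytokine list had 19 higher and 1 lower of 21 (median 1.90, adjusted p = 2.54e-11), the chemokine gene CXCL8 rising by 4.76 and IL1B, the one that fell, by 1.05. The ATF4 list had 22 higher and 2 lower of 24 (median 0.91, adjusted p = 2.00e-21). PPP1R15A, which restores translation after stress, rose from 34.5 to 395 CPM, and the 2 that fell were CHAC1 (-0.38) and SLC7A5, an amino acid transporter gene (-0.39). The NRF2 and xenobiotic list had 20 higher and 2 lower of 22 (median 1.52, adjusted p = 4.07e-25), CYP1A1, of xenobiotic metabolism, rising by 5.77 and HMOX1 from 3.18 to 91.1 CPM. Autophagy and lysosome had 18 higher and 5 lower of 24 (median 0.68, adjusted p = 1.21e-07), SQSTM1, a cargo receptor gene, rising by 2.82. Of 19 p53 targets 12 rose and 2 fell, or 13 and 2 adjusted over the list alone (median 0.73, adjusted p = 0.000423), CDKN1A from 11.3 to 68.9 CPM. The hypoxia list (5 higher and 1 lower of 11, median 0.18, adjusted p = 0.00340), apoptosis regulators (14 and 6 of 23, median 0.58, adjusted p = 0.0101) and immediate-early genes (15 and 2 of 18, median 1.16, adjusted p = 0.000594) rose with the preset correlation. Their calls were lost with an estimated correlation (adjusted p = 0.0700, 0.143 and 0.143). VEGFA rose from 99.0 to 588 CPM, BMF, a death gene, by 3.50, and DUSP1, a phosphatase gene, by 4.18, while BCL2 fell by 1.97.

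MYC targets had 0 higher and 52 lower of 52 (median -1.17, adjusted p = 8.01e-29), NOP16, of ribosome assembly, falling by 2.37. The tricarboxylic acid cycle had 0 and 18 of 21 (median -0.52, adjusted p = 0.000120), DLAT, of pyruvate dehydrogenase, falling by 0.96, and the respiratory chain 2 and 35 of 37 (median -0.65, adjusted p = 7.01e-08), ATP5MC1, of ATP synthase, by 1.70. Mitochondrially encoded messages had 1 and 10 of 13 (median -0.60, adjusted p = 1.50e-05, but adjusted p = 0.145 with an estimated correlation), with the oxidase gene MT-CO2 falling by 1.36 and MT-ND4, of complex I, rising by 0.23. Mitochondrial ribosomal RNA took 0.944 to 0.979% of counts with CWI1-2 and 0.217 to 0.230% with DMSO, the other way. Glycolysis had 4 and 16 of 23 (median -0.58, adjusted p = 5.51e-08), SLC16A1, a lactate transporter gene, falling by 1.52, and cholesterol synthesis 3 and 17 of 21 (median -0.66, adjusted p = 7.44e-10). G1/S and replication genes had 2 and 23 of 29 (median -0.66, adjusted p = 7.13e-08), UHRF1, of DNA methylation maintenance, falling by 1.46. The heat shock list had 4 and 10 of 14 (median -0.67, adjusted p = 4.75e-05), HSPA8 falling by 1.48 and HSPA1B rising by 1.35. Granulocyte and granule genes had 0 and 8 of 9 (median -1.65, adjusted p = 9.13e-29), the elastase gene ELANE falling by 2.28. The glutamine list had 6 and 18 of 25 (median -0.33, adjusted p = 0.0477, and adjusted p = 0.143 with an estimated correlation), SLC38A5 falling by 2.23 and SLC3A2, partner of amino acid transporters, rising by 1.41.

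**Figure D4:**
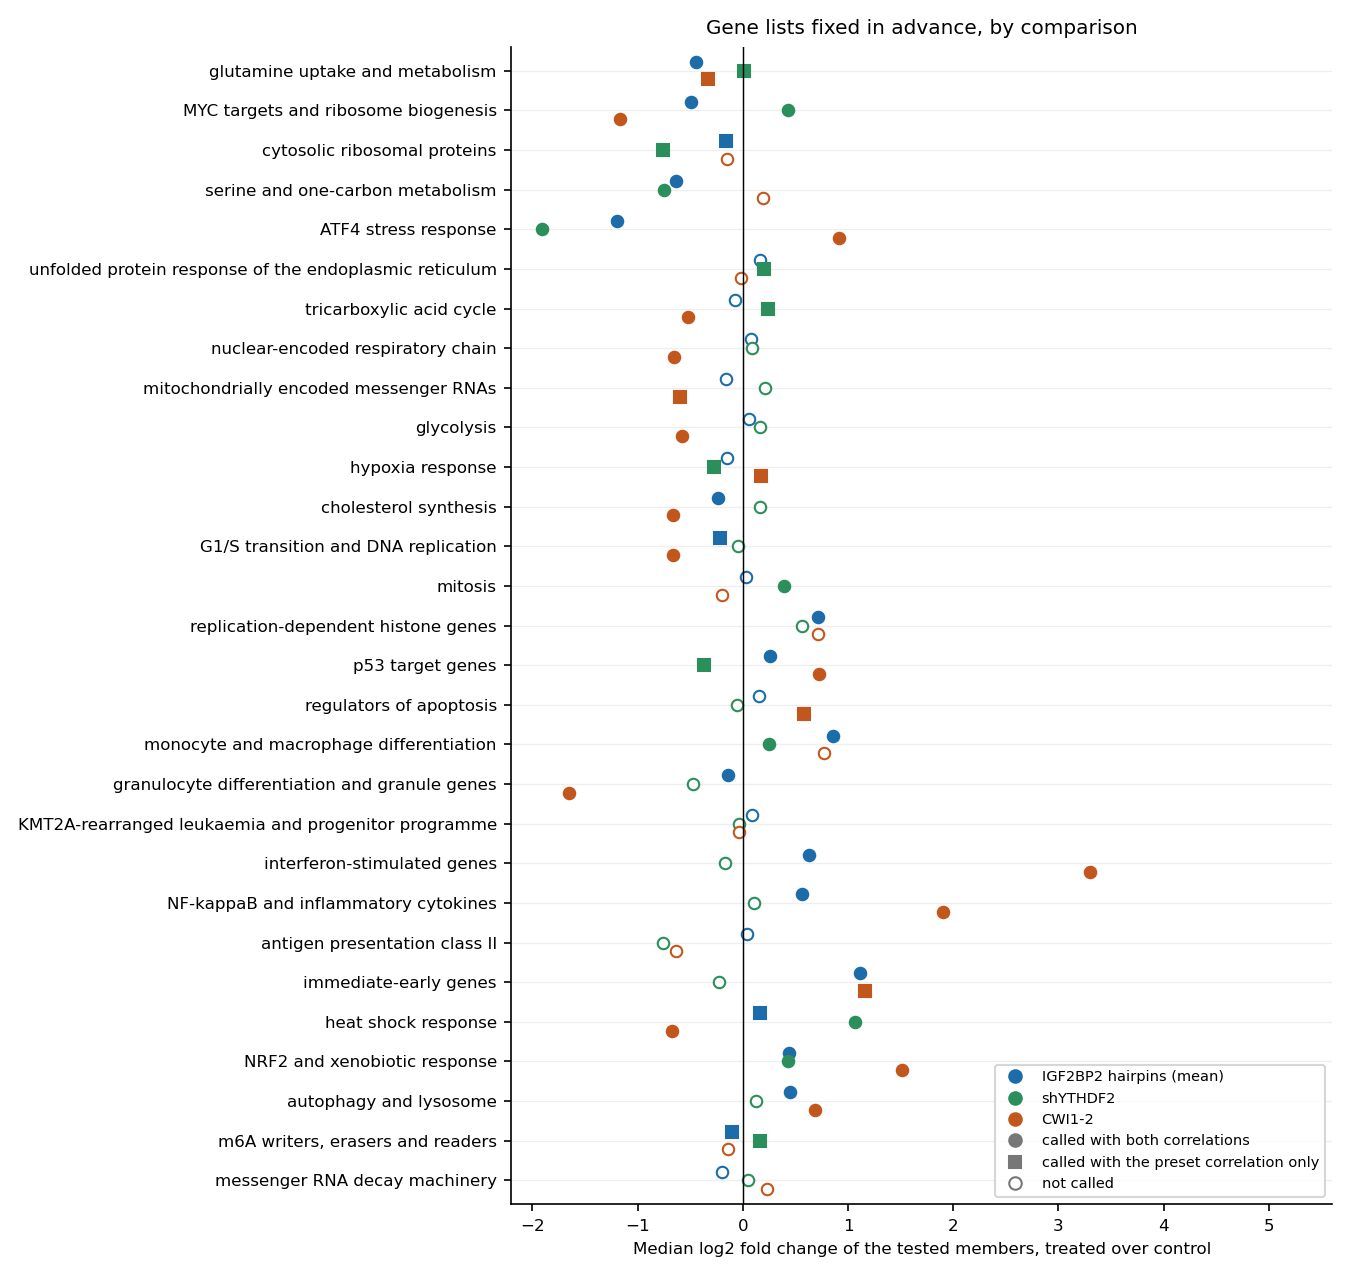
Median log2 fold change of the tested members of each gene list with at least 5 tested members, cell marker lists left out, for the mean of the 3 IGF2BP2 hairpins (blue), shYTHDF2 (green) and CWI1-2 (orange). Filled circles passed with both the preset and the estimated correlation, squares with the preset one only and open circles with neither; the interferon list stands at 3.30 under CWI1-2 and the ATF4 list at -1.20, -1.91 and 0.91 in the 3 comparisons.

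Lists that did not pass had, higher and lower, 12 and 31 of 52 for ribosomal proteins (adjusted p = 0.0728), a list that passed without CWI1-2 replicate 2 (adjusted p = 0.0497) or DMSO replicate 3 (adjusted p = 0.0310). The serine list had 8 and 7 of 15 (median 0.19, mean -0.13, test downward, adjusted p = 0.210). The unfolded protein response had 9 and 9 of 19 (median -0.01, or 0.08 scaled by library totals, mean 0.16, test upward, adjusted p = 0.30) and the KMT2A list 8 and 8 of 22 (median -0.04, or 0.05 scaled by library totals, adjusted p = 0.632), MYB, a factor of blood progenitors, falling from 799 to 226 CPM. Monocyte genes went both ways, 15 and 9 of 26, or 16 and 9 adjusted over the list alone (adjusted p = 0.160), the alarm protein gene S100A9 falling from 774 to 158 CPM. Mitosis had 5 and 16 of 29 (adjusted p = 0.293), histones 7 and 1 of 13 (adjusted p = 0.455), class II genes 1 and 7 of 9 (adjusted p = 0.30), the m6A list 8 and 11 of 23 (adjusted p = 0.274) with FTO, an RNA demethylase gene, falling by 0.90, and messenger RNA decay 16 and 8 of 29 (adjusted p = 0.0982) with XRN1, an exonuclease gene, rising by 1.26. Too few cell markers were measured for a list test. Of T cell and natural killer cell markers 2 of 2 rose, IL7R, the interleukin-7 receptor gene, by 1.94 and NKG7 by 0.32. Neither of 2 B cell markers passed, and 1 of 4 epithelial and stromal markers rose and 2 fell. Of erythroid and megakaryocyte markers 2 of 2 fell, KLF1 (-1.17), a call lost without CWI1-2 replicate 1 (-0.93) or DMSO replicate 1 (-0.99), and EPOR (-0.30), a call lost without CWI1-2 replicates 2 or 3 or DMSO replicates 1 or 2 (-0.27 to -0.26).

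The authors' CWI1-2 table lists 3272 lower genes, of which 3146 were tested here and 3137 fell, and 3127 higher genes, of which 2828 were tested here and 2827 rose.

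The last comparisons ask whether the compound and the libraries labelled shYTHDF2 share genes with the IGF2BP2 hairpins. MPO (-2.47 and -3.72), BCL2 (-1.74 and -1.97), MS4A3 (-1.74 and -3.48) and PRTN3 (-1.73 and -4.76) fell with both IGF2BP2 hairpins and CWI1-2. LILRB3 (2.61 and 5.76), FN1, which encodes fibronectin (2.37 and 2.64), and ITGB7, an integrin gene (2.21 and 3.58), rose with both. CHAC1 (-3.45 and -6.0), ALDH1L2 (-3.09 and -3.66) and ASNS (-2.70 and -3.01) fell both with IGF2BP2 hairpins and in shYTHDF2 libraries. CHAC1 and ASNS are on the ATF4 list, which lay higher in the shNS libraries of both experiments than in DMSO. Its median log2 was 1.23 for the YTHDF2 shNS libraries over DMSO, and -0.84 for DMSO over the IGF2BP2 shNS libraries. The part of such shared falls that stems from the controls was not tested.

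Of 13242 genes tested in both, 524 were higher and 753 lower with all 3 IGF2BP2 hairpins and CWI1-2, against 358 and 440 from the products of the shares, and 561 went opposite ways against 797. Tested as sets under CWI1-2, the genes higher with all 3 hairpins rose (median 0.25, adjusted p = 9.40e-06) and those lower fell (median -0.38, adjusted p = 1.01e-07), also with an estimated correlation (adjusted p = 0.0134 and 0.00347). Across genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.34 and Spearman's rho = 0.27. With IGF2BP2 hairpins and shYTHDF2, 309 genes were higher and 375 lower in both, against 213 and 248, and 493 opposite against 464. As sets in the shYTHDF2 fit the genes higher with all 3 hairpins rose (median 0.07, adjusted p = 0.00681) and those lower leaned downward (median -0.01, adjusted p = 0.00173; adjusted p = 0.00204 for both with an estimated correlation), although only 50.5% of the latter lay below 0, with 375 falling and 317 rising. Across genes r was 0.19 and rho 0.08. CD163 (2.32 and 2.60), SCD5, a desaturase gene (2.12 and 1.98), and KCTD12 (1.96 and 2.43) rose in both.

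CWI1-2 and shYTHDF2 went opposite ways more often than alike. Among 13087 genes, 751 were higher and 731 lower in both, against 1033 and 1000, while 2917 were opposite against 2036. The shNS libraries of the YTHDF2 experiment differed from DMSO in the direction of CWI1-2 for ATF4 (median log2 1.23), MYC target (-0.37) and heat shock (-1.56) genes. The serine list also lay higher there (0.80), but it was not called under CWI1-2. Opposite signs in such genes can stem from that control, and the part that does was not tested. Genes higher under CWI1-2 fell as a set in the shYTHDF2 fit (median -0.08, adjusted p = 0.000638, but adjusted p = 0.0602 with an estimated correlation) and those lower rose (median 0.11, adjusted p = 3.87e-05, and 0.00204 as adjusted p with an estimated correlation). THBS1 (5.34 and 3.97), HMOX1 (4.84 and 3.07), C3 (3.73 and 4.65) and IL4I1, an amino acid oxidase gene (3.20 and 2.14), rose in both, and RAB37, of vesicle traffic (-1.21 and -1.81), and NTSR1, the neurotensin receptor gene (-2.35 and -1.17), fell in both.

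**Figure D5:**
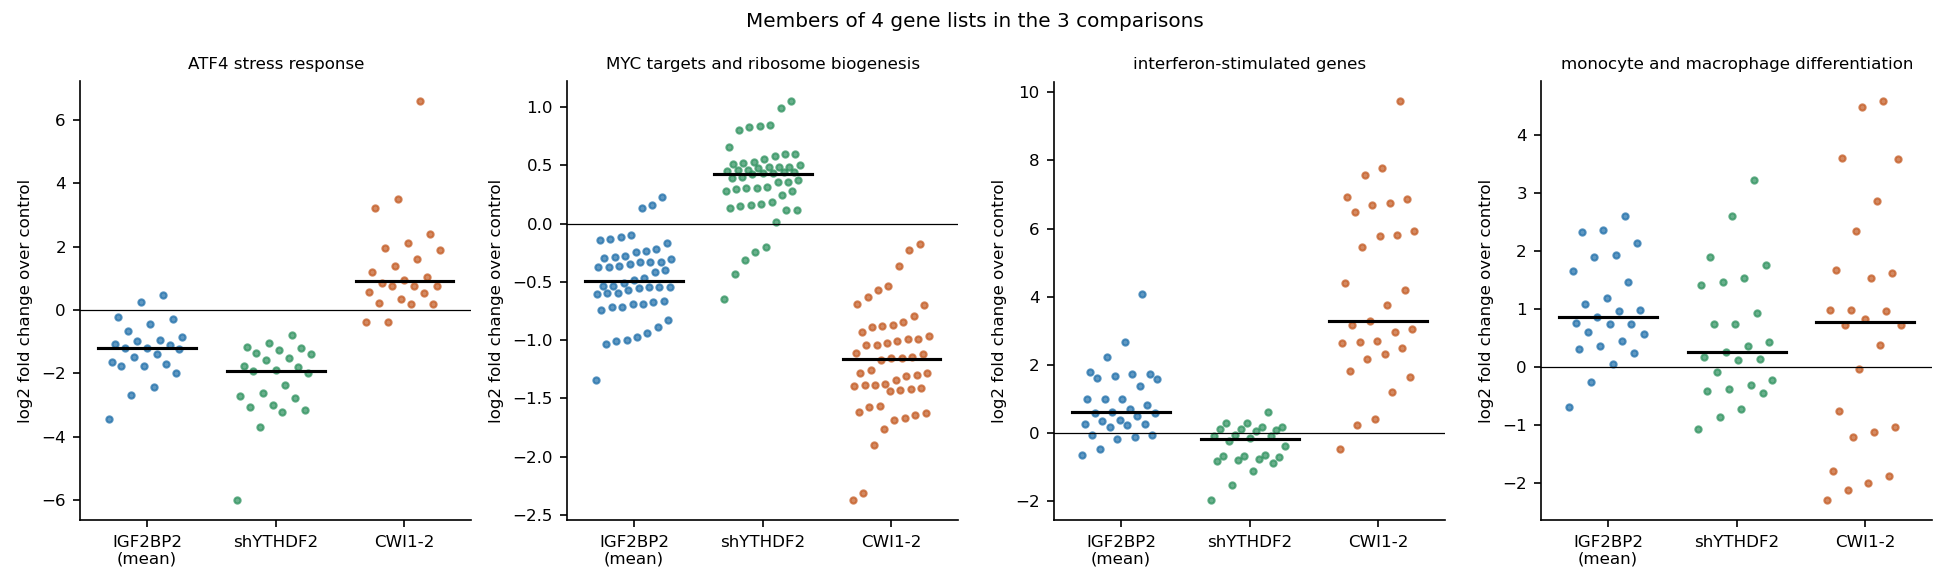
Log2 fold change of each tested member (points) of 4 gene lists in the 3 comparisons, with the median as a black line; each panel has its own scale. The ATF4 list has its median at -1.20, -1.91 and 0.91 and the MYC target list at -0.49, 0.43 and -1.17 for the IGF2BP2 hairpins, shYTHDF2 and CWI1-2.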

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

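Chosen only after the results were seen were the word scans, the tests of reads moved to partner genes, of a raised control, of a wrong label and of other blood cells, and the target and 3' UTR checks for sh1 and sh3. The target and 3' UTR checks for sh2 were set after its word was found but before their own results were seen; the others were set before. SOCS3, IDH1, PECAM1 and RPL14 had some of the smallest p-values for a difference between the 3 IGF2BP2 hairpins (edgeR F test, adjusted p = 4.79e-47, 7.69e-45, 7.69e-45 and 1.16e-44). Among the hairpins IDH1 (log2 -1.76 against shNS), PECAM1 (-1.07) and RPL14 (-2.42) were lowest in the 3 libraries with sh2, and SOCS3 (-2.43) was lowest with sh3.

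The first pattern is a set of 337 genes lower with sh2 alone, at least 1 log2 unit below both other hairpins, with a mean of at least 5 CPM. Moved reads and a GC or length trend were argued against: pseudogenes and overlapping genes regained 0.760% (SD 0.316) of the 24292 CPM lost, and 94.7% of the genes stayed at least 2-fold below the mean of the other hairpins after removal of GC and length trends of up to 0.548. A candidate explanation is an off-target effect of the hairpin's seed, since the word CCGGAAA lay in the transcripts of 123 of these genes against 36.6 expected and in 4 of 4 protein-coding IGF2BP2 transcripts (coding sequence, chromosome 3, 185675400 to 185675406, minus strand). The word was found by scanning these same genes, after exploratory scans with other thresholds, gene sets and word lengths; the hairpin sequences are not in the labels, and as a word in 3' UTRs outside the set it ranked 122 of 16133, which left this open. For sh1 the top word GGGAAAC (75 of 166 genes, 40.3 expected) also lay in 4 of 4 IGF2BP2 transcripts and ranked 3 of 16144 in 3' UTRs outside the set. Each of these transcripts held at most 1 site of either word. GGGAAAC lay in 24.3% of other genes and CCGGAAA in 10.9%, so a site in the target can also occur without a seed match. For sh3 the top word CGTACCC (12 of 97 genes, 4.02 expected) lay in 0 and ranked 6435 of 16147, which argues against it as a seed match.

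The second pattern is the ATF4 list, lower in all 24 genes in the libraries labelled shYTHDF2. A GC or length trend was argued against, since the median of all 24 genes was -1.91 after correction. Of these, 20 had GC and length values, and the rest were left uncorrected. A raised control alone was argued against by the median of -0.92 (SE 0.15) against DMSO, with 21 of 24 genes lower. However, the shNS libraries lay 1.23 above DMSO, so differences of this size also occur between control groups. Over 14996 genes the shYTHDF2 libraries lay closer to DMSO (root mean square log2 distance 0.516) than to their own shNS libraries (0.625). Those shNS libraries lay 0.611 from DMSO, so the part of the whole contrast that stems from the control is not known. A wrong label or a hairpin that left YTHDF2 mRNA in place stayed open, since YTHDF2 differed by -0.15 (SE 0.06). The protocol calls these cells KO but describes shNS and shYTHDF2 lentiviruses; a knockout can leave the mRNA in place, and this stayed open too. Loss of YTHDF2 is the explanation the design names, and it may act with or without these; it was not tested otherwise.

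The third pattern is the interferon list, higher under CWI1-2. A GC or length trend was argued against by a median of 3.43 after correction (3.30 before). RNA of T cells, B cells or red cells as the whole cause was argued against: of 7 abundant transcripts of these cells, HBA2 gained most, from 0.258 to 0.774 CPM, which is 0.592% (SE 0.260) of the median gain of the interferon list (87.3 CPM). CD3D, CD3E, MS4A1 and HBB had 0 counts. The bound was a gain under 10% of that median; a first bound, a level under 0.1 CPM for each transcript with CWI1-2, which HBA2, HBA1 and CD79A did not meet, was tighter than the size of the rise requires. The compound is the explanation the design names, and it was not tested otherwise.

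Other splits of the same libraries were counted. In the IGF2BP2 experiment 1 of 60 splits, the real one, gave as many calls: 7947 genes for sh1 (highest other 4457), 8985 for sh2 (337), 7122 for sh3 (1087), 7612 for the mean (941), 2229 with all 3 hairpins (251) and 11318 between hairpins (4907). At 0.05 this argues only against labels unrelated to the libraries. Other splits mix groups that differ, which widens the spread within groups and lowers their calls. Differences between cultures are not excluded, since the labels do not say that replicates are separate cultures. For genes shared with CWI1-2 (1277, highest other 145) and with shYTHDF2 (684, highest other 129) the splits decide nothing, since no other split called as many with all 3 hairpins. Nor do they for the 2917 genes of shYTHDF2 and CWI1-2 that went opposite ways (1 of 100 splits, highest other 0), since no other split of either experiment called a gene. For this test lists were adjusted within each comparison, which changes their number. List calls for the mean numbered 19 against a highest other of 17, so the preset correlation also called many lists in other splits. For shYTHDF2 (5690 genes, highest other 0; 13 lists, highest other 11) and CWI1-2 (9768 genes, highest other 0; 19 lists, highest other 17) the 10 splits are too few for a share under 0.05.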

How the results depend on the processing

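The alternative with sh1 and sh3 only was chosen after seeing the data; the others were set before. Of 480 named gene values, 479 kept their call, and its direction where called, with DESeq2 size factors, 473 with library totals, 460 with the DESeq2 test, 477 with limma-voom, 466 without a filter and 474 with a replicate block. Over all alternatives, values not called under either setting changed sign in 40 cases. Library totals moved the median log2 change of all genes to 0.104 for sh2 and 0.102 for CWI1-2, with 5297 genes higher and 3729 lower for sh2 and 5573 and 4249 for CWI1-2, so the even balance of directions depends on the scaling.

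A 1.5-fold threshold left 1650 genes higher and 1717 lower for sh1, 2436 and 1977 for sh2, 1287 and 1308 for sh3, 1215 and 984 for the mean, 314 and 204 with all 3 hairpins, 902 and 1342 for shYTHDF2, 2758 and 2610 for CWI1-2, and 7122 that differed between hairpins. It left 159 higher, 74 lower and 67 opposite shared by CWI1-2 and all 3 hairpins, 72, 91 and 34 by shYTHDF2 and all 3 hairpins, and 163, 144 and 802 by shYTHDF2 and CWI1-2; the stricter threshold is the reason. An adjusted p threshold of 0.01 left 1947 higher for shYTHDF2, 173 higher and 293 opposite shared with all 3 hairpins, and 435 and 430 shared with CWI1-2. Fitted as 9 libraries against 3, the mean had 785 higher and 788 lower, since differences between hairpins then counted as spread.

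With an estimated correlation the genes higher under CWI1-2 no longer passed as a set for shYTHDF2 (adjusted p = 0.0602), and fry called 83 lists. Lists whose direction for the mean of the hairpins reversed were the unfolded protein response with fry (adjusted p = 0.0423), ribosomal proteins (0.330) and mitosis (0.00226) with sh1 alone, cholesterol synthesis with sh2 alone (0.657), and NF-kappaB (0.0675) and class II genes (0.0131) with sh3 alone. With sh1 and sh3 only, 2053 genes were higher and 2058 lower in both, and log2 changes reversed for RPS20 (0.14), PFKL (0.10), SQLE (-0.066), CCNA2 (0.010), MX2 (0.038), FTO (-0.19), TRAC (-2.33) and VIM (0.36), since sh2 had moved them the other way; the value of TRAC rests on 0 counts with sh3 and is no bound. Other causes were not tested.

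With a replicate block 3434 genes were higher and 4092 lower for the mean, 2787 and 2707 for shYTHDF2 and 4902 and 4859 for CWI1-2. Replicate numbers did not pair the samples: residuals of libraries with the same number correlated at -0.107 to 0.0528 in the IGF2BP2 experiment, -0.0281 to 0.0246 in the shYTHDF2 experiment and 0.0243 to 0.0662 in the CWI1-2 experiment (-0.0543 to 0.0125 for other pairs there), all under 0.1. Libraries correlated best with their own number in 12 of 36, 3 of 6 and 6 of 6 cases, the last a hint from the data, not the design. Leaving out 1 library gave 2944 to 3460 higher and 3667 to 4260 lower for the mean, 879 to 1006 and 1033 to 1241 with all 3 hairpins, 2236 to 3171 and 2154 to 3014 for shYTHDF2, 4692 to 4809 and 4711 to 4808 for CWI1-2, and 49 to 56 lists.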

Other observations

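The gene families and the word scans were chosen only after the results were seen; the test of the UGGAC hypothesis was set before. Genes lower with all 3 IGF2BP2 hairpins could carry more UGGAC, a core of the m6A motif, in their 3' UTRs. The test was negative: their mean density was 0.910 sites per kb in 1003 genes against 0.922 in uncalled genes of like length (difference -0.0119, permutation p = 0.792, two-sided, 10000 draws).

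Of 72 tests of gene families, 29 passed with the preset correlation and 3 with an estimated one. Cytosolic aminoacyl-tRNA synthetases fell with the IGF2BP2 hairpins (0 higher and 18 lower of 20, median -1.16, adjusted p = 2.17e-72, and adjusted p = 2.93e-06 with an estimated correlation) and in shYTHDF2 libraries (3 and 12 of 20, median -0.82, adjusted p = 9.31e-21 and 0.0222). Of this family, WARS1, AARS1, SARS1 and CARS1 are also on the ATF4 list, so these calls are not independent of that list. Genes named EIF, which are translation initiation factors and some of their regulators, such as EIF4EBP1 (-1.90), fell with the hairpins (8 and 32 of 60, median -0.21, adjusted p = 2.51e-05 and 0.0146). Under CWI1-2 CCT chaperonin subunits (0 and 8 of 8, median -0.96) and genes named TUBA or TUBB with a number (1 and 9 of 11, median -1.50) passed with the preset correlation only (adjusted p = 0.0514 for both with an estimated one).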
